A study of Mus musculus with 6 samples.

How the data were processed

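Lung RNA from 6 smoke-exposed mouse samples was sequenced, 3 wild-type and 3 FTO-overexpressing, and 1 table of values per gene was used. Per the labels' protocols, total RNA was extracted with TRIzol, a phenol-based reagent, its quality was checked, and libraries were made with a stranded Illumina kit that selects polyadenylated RNA. The submitters' processing notes name fastp (trimming of reads), HISAT2 (spliced alignment) and StringTie (transcript assembly and quantification), without versions. The genome build, the annotation release and the program that made the gene table are not given in the sources used here, so no genomic positions are printed and genes are named by the identifiers and symbols that the table pairs. Whether the counting used the strand is not given either, so reads of overlapping or antisense genes cannot be told apart where it did not.

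The values the authors deposited are expected counts, that is estimated read counts per gene that need not be whole and are not scaled to library size. Between 9.66% and 10.3% of the rows of a library were not whole, and column totals differed between libraries from 16731850 to 21444907. The table held 57180 rows. 525 rows had no gene symbol and took 0.119% to 0.143% of the counts of a library. 29537 rows had counts. Poly(A) selection favours intact messenger RNA, so transcripts without a poly(A) tail are not measured well, and genes with near-identical copies, such as the haemoglobin genes, can share reads.

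Values were rounded to whole numbers before the count tests. Each column was matched to its sample by the column name that the sample's label gives, and groups were taken from the genotype label. In R 4.3.3, edgeR 4.0.16 was used with its default filter on low counts (filterByExpr with the group), TMM scaling and the quasi-likelihood F-test, with group as the only term. 16989 genes were tested, p-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Fold changes are fitted values with 95% intervals, and levels are TMM-normalised read counts in CPM with the SD over 3 libraries. Standard errors (SE) and intervals were derived from the log2 fold change and its F statistic, so they rest on the same test as the p-value. The common biological coefficient of variation was 0.190. Intervals cover the spread between these libraries, and no molecular identifiers were used. Libraries of 1 group differed from each other by far more than counting noise (chi-square over degrees of freedom of 31.0 to 54.0 within groups), so none was treated as a duplicate of another. Pairs across groups gave 23.0 to 51.8, lowest for replicate 1 of both groups, so libraries did not separate by group on this measure.

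The comparison, its alternatives, the rule for naming genes and 56 gene lists were fixed before the data were examined. Lists covered m6A machinery, smoke responses, cell death, stress, matrix, lung and immune cell types, and tissues that can enter a lung dissection. Of 981 list entries 980 were found, with older symbols matched through reference gene names; 64 symbols stand in more than 1 list. The 53 lists with at least 5 members tested were compared with all other genes by camera (limma 3.58.1), two-sided, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over lists. Camera was repeated with an estimated correlation, and fry was run in its directional and mixed forms. For each list the members past 0.05 over all genes and adjusted over the list alone were counted.

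Named genes were Fto, up to 12 genes in each direction with the largest fold change among those past the threshold, and members of the lists. The first kind needed an average log2 CPM of at least 1 and all libraries of 1 group above those of the other, and left out predicted or clone-named loci and variable segments of immunoglobulin and T cell receptor genes. 11 higher and 3 lower genes met it. For each list past camera, up to 4 members past 0.05 adjusted over the list alone were named, or the 2 with the smallest p where none passed, given as values. For lists described as not passing, up to 2 members were named. Genes outside this rule are said to have been chosen after their values were seen.

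The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (a mean of at least 50 counts), the replicate number as a block, haemoglobin, immunoglobulin and mitochondrial genes left out, each library left out in turn, limma-voom, DESeq2 1.42.0 and thresholds of 0.01 and 0.1. The procedure was tested on simulated counts for the same 16989 genes and library sizes. It recovered 77% of 100 genes changed 2-fold and 97% of 100 changed 4-fold. It made 186 calls, of which 11 were false and 0 had the wrong sign. The data gave 16 calls, and fewer calls make the Benjamini-Hochberg cutoff stricter. The recovery rates therefore need not hold in the data. The changed genes were drawn from genes outside the lists with a mean of at least 50 counts, so recovery among weaker genes was not measured. A list of 16 genes shifted by 0.5 on the log2 scale was called, and 0 other lists were. Each gene was simulated independently of the others. In the data the estimated correlation between members was 0.62 for T cell markers, 0.461 for cytotoxic cell markers and 0.777 for the cell cycle. The simulation therefore cannot show how often camera with the preset of 0.01 falsely calls correlated lists. Figures were drawn with matplotlib 3.10.9.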

Results

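Polyadenylated RNA was sequenced from 6 mouse lung samples, all from animals exposed to cigarette smoke. 3 samples came from wild-type animals and 3 from animals overexpressing FTO, the enzyme that removes the methyl group of N6-methyladenosine (m6A) from RNA. The study modelled chronic obstructive pulmonary disease, and its 1 comparison asked which lung transcripts differed when FTO was overexpressed during smoke exposure. Unexposed lungs were not analysed here, so no value below measures an effect of smoke. The wild-type libraries held 18951310, 19389115 and 18044267 counts and the FTO-overexpressing libraries 20306682, 16731850 and 21444907. The labels do not say that each library came from a separate mouse, and the p-values then measure the spread between these samples only.

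Fto itself (ENSMUSG00000055932) was measured at a normalised read count (CPM) of 68.2 ± 1.85 (SD, n = 3) in wild-type lungs and at 685.7 ± 48.4 CPM (SD, n = 3) in FTO-overexpressing lungs. The difference was 10.05-fold (95% interval 8.66 to 11.7), with an edgeR adjusted p of 1.45e-05. It ran from 66.2 to 69.9 CPM among the wild-type libraries and from 650.1 to 740.8 CPM among the overexpressing ones, so each library carried the level its label called for. How the overexpression was made is not given in the labels, and a count per gene does not separate introduced from endogenous transcripts. The other genes of the m6A machinery did not follow Fto. Among 22 writers, readers and the other eraser, 0 changed when p was adjusted over the list alone, and their median log2 fold change was -0.014 (camera adjusted p = 0.717). Virma, a subunit of the methyltransferase complex, had a log2 fold change of 0.17 ± 0.070 (SE), and that of Igf2bp3, an m6A reader, was 1.45 ± 0.636 (SE), with edgeR adjusted p of 0.507 and 0.546.

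Genes of CD8 T cells and cytotoxic lymphocytes rose in FTO-overexpressing lungs. Cd8a (ENSMUSG00000053977) and Cd8b1 (ENSMUSG00000053044), the subunits of the CD8 co-receptor, were 7.03-fold (95% interval 4.28 to 11.6) and 8.58-fold (95% interval 4.80 to 15.3) higher. Cd8a stood at 9.81 ± 2.63 CPM in wild-type and 69.0 ± 24.6 CPM in overexpressing lungs (SD, n = 3 each). Ccl5 (ENSMUSG00000035042), a chemokine made by activated T cells, rose 14.7-fold from 11.0 ± 3.22 to 161.4 ± 61.9 CPM (SD, n = 3 each). Klrc1 (ENSMUSG00000030167), which encodes the receptor NKG2A of natural killer (NK) and CD8 T cells, rose 14.3-fold from 2.57 ± 0.829 to 36.9 ± 11.1 CPM. Klrg1, a receptor of differentiated effector lymphocytes, was 11.05-fold higher, and Tbx21, which encodes the effector transcription factor T-bet, 8.44-fold higher. The NK receptor gene Klrk1 was 5.52-fold higher, the death ligand gene Fasl 4.90-fold, the T cell receptor kinase gene Lck 4.89-fold and the chemokine receptor gene Cxcr6 3.35-fold. The edgeR adjusted p of these 10 genes lay between 0.0169 and 0.0363. Each was higher in 3 of 3 overexpressing libraries than in any wild-type library, which the naming rule required. All 10 calls were lost, with the direction kept, in the fits without wild-type replicate 2, wild-type replicate 3 or overexpressing replicate 2. Those of Cd8a, Cd8b1, Klrg1, Tbx21, Fasl, Lck and Cxcr6 were also lost without wild-type replicate 1. Without overexpressing replicate 3 those of Cd8a, Cd8b1, Tbx21, Klrk1 and Fasl were lost. Over all fits without 1 library the highest edgeR adjusted p was 0.183, for Tbx21. All 10 were also lost with the replicate number as a block, and 9 with limma-voom, where only Ccl5 kept its call.

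In all, 16 of 16989 genes tested passed an edgeR adjusted p of 0.05, of which 13 were higher and 3 lower, and 15 differed at least 2-fold. Without adjustment, 1603 genes had p under 0.05. The 16 called genes include Ifng, 9.89-fold higher but too weakly expressed for the naming rule (0.289 ± 0.118 against 2.90 ± 0.567 CPM, adjusted p = 0.0361), and a predicted locus that the rule leaves out. The number of calls rested on few libraries and on the tool: 1 gene, Fto, passed without wild-type replicate 2, wild-type replicate 3 or FTO-overexpressing replicate 2, and 6 and 49 passed without overexpressing replicates 3 and 1. DESeq2 called 420 genes, among them all 16, limma-voom called 5, and a fit with no filter on low counts called 287.

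**Figure D1:**
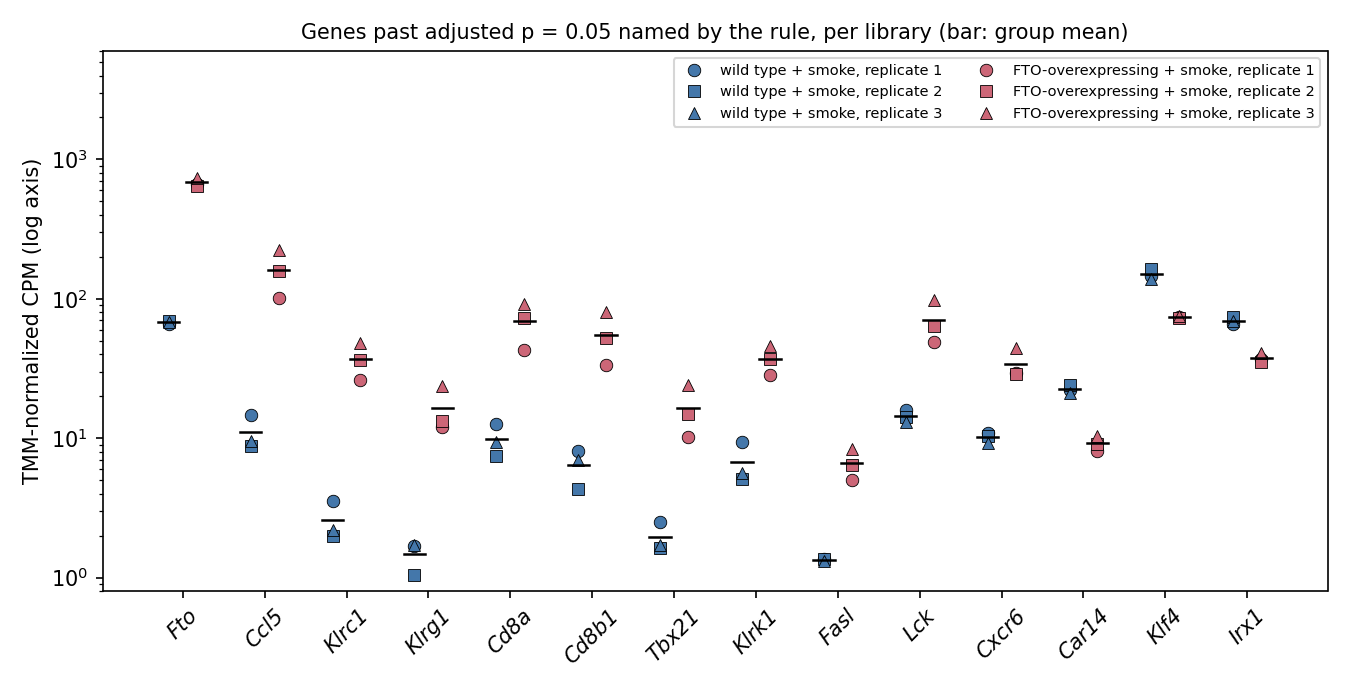
Level of each gene called by edgeR and named by the rule, as normalised read count (CPM) on a logarithmic axis; each point is a library (circle, replicate 1; square, replicate 2; triangle, replicate 3), blue for wild-type and red for FTO-overexpressing lungs, and bars are group means. The 11 higher genes (Fto to Cxcr6) and the 3 lower genes (Car14, Klf4 and Irx1) each have all 3 libraries of one group above all 3 of the other. The naming rule required this.

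T cell markers, cytotoxic cell markers and cell cycle genes each rose together. Of 20 T cell markers, 18 rose when p was adjusted over the list alone, 3 of them also over all genes (Cd8a, Cd8b1 and Lck), and the median member was 3.07-fold higher. Themis, a T cell receptor signalling adaptor, was 5.44-fold higher (95% interval 3.17 to 9.33). Of 14 NK and cytotoxic markers, 11 rose by the same measure, with a median of 4.52-fold. Gzma, the gene of the killing protease granzyme A, was 9.24-fold higher (95% interval 4.85 to 17.6), at 12.2 ± 6.51 against 112.9 ± 41.8 CPM (SD, n = 3 each). All 26 cell cycle genes rose over the list alone, though 0 of them over all genes, with a median of 2.48-fold. Among them the ribonucleotide reductase subunit gene Rrm2 was 3.08-fold, the mitotic kinesin gene Kif20a 2.74-fold, the cyclin gene Ccna2 2.71-fold and the spindle assembly gene Tpx2 2.61-fold higher. The camera adjusted p was 2.87e-47 for T cells, 2.33e-47 for cytotoxic cells and 1.04e-49 for the cell cycle with a preset correlation of 0.01. With an estimated correlation the adjusted p was 0.173 for T cells, 0.173 for cytotoxic cells and 0.212 for the cell cycle. The estimated correlations were 0.62, 0.461 and 0.777 in that order, far above the preset. Directional fry gave an adjusted p of 0.125 for each of the 3 lists. Of the camera and directional fry tests, only camera with the preset correlation passed these lists. There they stayed past the threshold without any 1 of the 6 libraries. The mixed form of fry does not ask members to share a direction. Its adjusted p was 0.0438 for T cells, 0.0205 for cytotoxic cells and 0.0499 for the cell cycle.

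B cell markers did not move with the T cell markers. Their median log2 fold change was -0.019, 0 of 16 members changed over the list alone, and the camera adjusted p was 0.843. Cd37 and Blnk had log2 fold changes of 0.32 ± 0.194 and -0.30 ± 0.280 (SE). The share of counts from haemoglobin genes, which reflects blood in the tissue, was 2.26%, 1.54% and 0.856% in the wild-type and 3.27%, 1.81% and 0.368% in the overexpressing libraries. It was lowest in the overexpressing library with the highest T cell level, replicate 3.

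**Figure D2:**
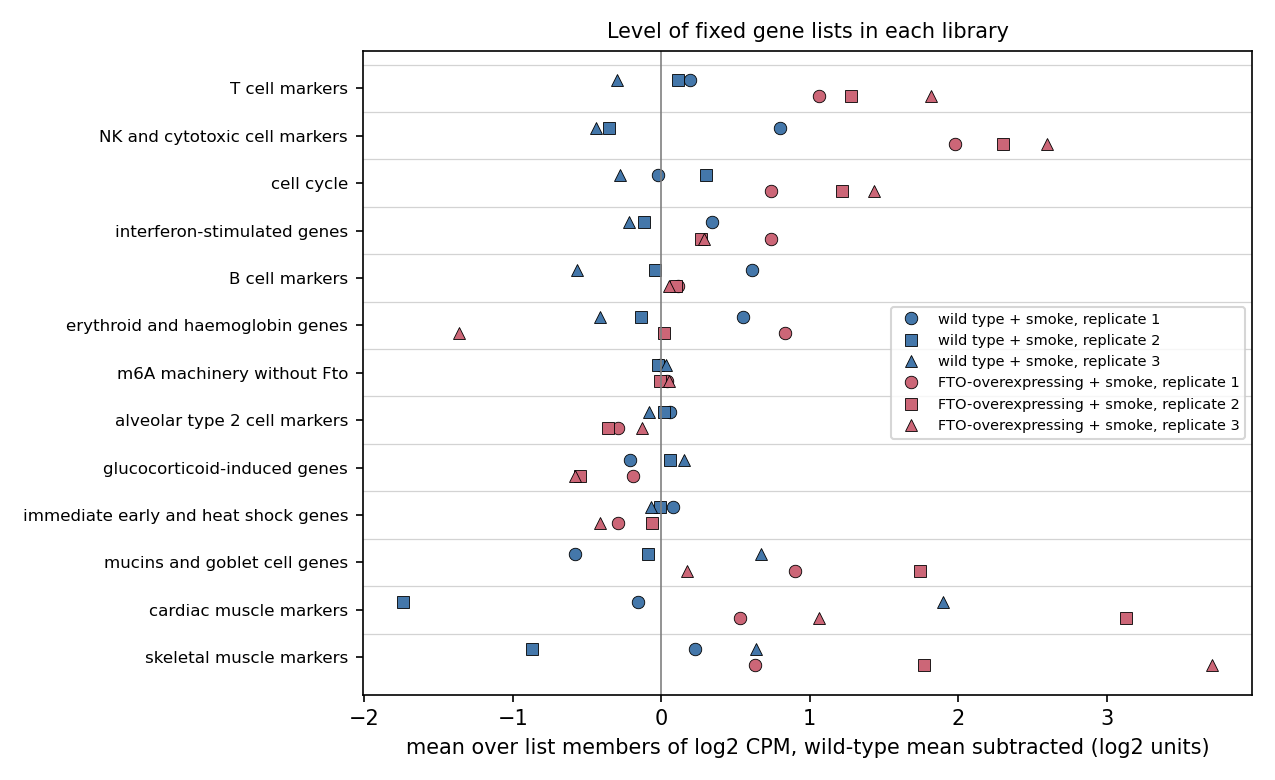
Level of 13 gene lists in each library, as the mean over members of log2 CPM after subtraction of the wild-type mean (horizontal axis, log2 units); blue points are wild-type and red points FTO-overexpressing libraries, with the replicate shown by the shape. T cell levels were 1.06, 1.28 and 1.82 in overexpressing replicates 1, 2 and 3 and at most 0.19 in the wild-type libraries, while B cell, haemoglobin and m6A machinery levels overlapped between the groups.

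3 genes fell past the threshold over all genes. Car14 (ENSMUSG00000038526), a membrane-bound carbonic anhydrase gene, was at 22.5 ± 1.67 CPM in wild-type and 9.20 ± 1.15 CPM in overexpressing lungs, a ratio of 0.409 (95% interval 0.332 to 0.504; edgeR adjusted p = 0.0266). Klf4 (ENSMUSG00000003032), a transcription factor gene of epithelium, endothelium and myeloid cells, fell from 149.9 ± 13.2 to 74.3 ± 1.43 CPM, a ratio of 0.496 (95% interval 0.432 to 0.569; edgeR adjusted p = 0.0179). Irx1 (ENSMUSG00000060969), a homeobox gene of lung development, fell from 69.7 ± 4.00 to 37.5 ± 2.84 CPM, a ratio of 0.538 (95% interval 0.469 to 0.618; edgeR adjusted p = 0.0244). Values are SD with n = 3 in each group. The 3 calls were lost, with the direction kept, without wild-type replicates 2 or 3 or overexpressing replicates 2 or 3, and those of Car14 and Irx1 also without wild-type replicate 1. All 3 were also lost with the replicate number as a block. Over the fits without 1 library the edgeR adjusted p was at most 0.155 for Car14, 0.123 for Klf4 and 0.155 for Irx1.

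Genes induced by glucocorticoids and immediate early genes were lower as lists. Of 15 glucocorticoid-induced genes, 3 fell over the list alone and the median log2 fold change was -0.37 (camera adjusted p = 4.51e-08, and adjusted p = 0.173 with an estimated correlation). Tsc22d3, which encodes the anti-inflammatory glucocorticoid mediator GILZ, fell from 222.1 ± 10.6 to 113.0 ± 19.9 CPM, a ratio of 0.509. The ratio was 0.527 for Errfi1, a feedback inhibitor of the epidermal growth factor receptor, and 0.655 for the transcription factor gene Klf15. Of 18 immediate early and heat shock genes, 3 fell over the list alone: Klf4, the phosphatase gene Dusp1 at a ratio of 0.576 and the chaperone gene Dnajb1 at 0.631. That list had a median of -0.27 (camera adjusted p = 1.56e-06, and adjusted p = 0.173 with an estimated correlation). It was -0.14 with limma-voom, with the call kept, and 4 of the 18 genes, Egr1, Egr2, Fosb and Junb, had log2 fold changes above 0. The levels of both lists overlapped between the groups. The immediate early list holds genes that respond to handling of the animals and tissue.

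Alveolar and vascular markers were slightly lower. The median log2 fold change was -0.25 over 14 alveolar type 2 cell markers, all of them below 0, and -0.21 over 20 surfactant genes, of which 9 stand in both lists and 0 changed over the surfactant list alone. 3 of the type 2 markers fell over the list alone: the surfactant protein gene Sftpd at a ratio of 0.741, the lamellar body transporter gene Abca3 at 0.817 and the lysozyme gene Lyz1 at 0.655. The medians were -0.17 for alveolar type 1 cells and -0.14 for endothelial cells, where Egfl7, a gene of the vessel wall, fell over the list alone at a ratio of 0.741. The endothelial median was -0.079 without overexpressing replicate 2, with the call kept (adjusted p = 0.00895), and the type 1 median ran from -0.12 without that library to -0.26 without overexpressing replicate 1. Among type 1 markers, which had 0 such members, the ratio was 0.753 for Rtkn2 and 0.825 for Emp2. The camera adjusted p was 4.51e-08 for type 2 cells, 1.06e-05 for surfactant, 0.000123 for type 1 cells and 0.000138 for endothelium. With an estimated correlation the adjusted p was 0.510, 0.467, 0.513 and 0.573. The mesothelial median was -0.72 (camera adjusted p = 0.000181, and adjusted p = 0.513 with an estimated correlation), with 0 of 7 members changed over the list alone. It ran from -0.39 without wild-type replicate 2 to -1.25 without wild-type replicate 1, and the list levels overlapped between the groups (-0.74, 0.55 and 0.19 against -0.43, -0.67 and -1.05). Its members Upk3b and Upk1b had ratios of 0.309 and 0.768, with overlapping groups.

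Interferon-stimulated genes were higher as a list and the myeloid lists went both ways, with 0 of their members changed over the list alone. All 27 interferon-stimulated genes had positive fold changes, with a median log2 fold change of 0.34 (camera adjusted p = 4.51e-08, and adjusted p = 0.582 with an estimated correlation). The median was 0.54 without wild-type replicate 1, and the list levels overlapped between the groups (0.34, -0.12 and -0.22 against 0.74, 0.27 and 0.29). Irgm1, an interferon-gamma-induced GTPase gene, was 1.99-fold and the antiviral gene Oas2 1.38-fold higher. Irgm1 was highest in overexpressing replicate 1, at 184.9 CPM against 86.1 and 80.3 CPM in the other two. Alveolar macrophage markers had a median of -0.24 and smoke-associated macrophage genes one of -0.31 (camera adjusted p = 0.000387 and 0.00106, and adjusted p = 0.637 and 0.513 with an estimated correlation). Both calls were lost without wild-type replicate 1 (medians of -0.15 and -0.15, adjusted p = 0.0567 and 0.0779), and the alveolar macrophage median ran from -0.14 without overexpressing replicate 3 to -0.42 without overexpressing replicate 1. The ratios were 0.787 for Car4, which endothelial cells also express, 0.702 for the cathepsin gene Ctsk, 0.687 for the osteopontin gene Spp1 and 0.714 for Gpnmb. Monocyte and interstitial macrophage markers had a median of 0.17 (camera adjusted p = 0.0317, and adjusted p = 0.650 with an estimated correlation), with 2.01-fold for Ly6c2 and 1.93-fold for Cx3cr1. That call was lost without wild-type replicate 3 or overexpressing replicates 1 or 3 (adjusted p of 0.217, 0.104 and 0.0885).

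Cytokines, apoptosis and ferroptosis passed camera narrowly and on few members. Of 28 cytokines and chemokines, 2 rose over the list alone, Ccl5 and the chemokine gene Ccl4 (2.64-fold, 0.558 ± 0.0739 against 1.47 ± 0.358 CPM), and the median was 0.025. That median turned to -0.13 without overexpressing replicate 1 and was 0.13 without wild-type replicate 1. Of 21 apoptosis genes, 1 rose, Fasl, which lymphocytes carry. Of 22 ferroptosis genes, 1 fell, Ptgs2, which encodes the prostaglandin synthase COX-2, at a ratio of 0.501. The medians of the apoptosis and ferroptosis lists were 0.12 and -0.053. Without 1 library the apoptosis median ran from 0.068 (overexpressing replicate 1) to 0.16 (wild-type replicate 1), and that of ferroptosis from -0.027 (overexpressing replicate 2) to -0.12 (overexpressing replicate 1). The camera adjusted p was 0.0486, 0.0486 and 0.0477 for the 3 lists, and with an estimated correlation the adjusted p was 0.582, 0.678 and 0.678. The TGF-beta and Wnt list had a median of -0.14 (camera adjusted p = 0.00982, and adjusted p = 0.491 with an estimated correlation), and 1 of 21 members, the matrix signalling gene Ccn2, fell at a ratio of 0.605. Without wild-type replicate 2 its median was -0.075 and the call was barely kept (adjusted p = 0.0497). Leaving out a single library ended the call for cytokines (adjusted p of 0.168 without wild-type replicate 1, 0.204 without wild-type replicate 3 and 0.361 without overexpressing replicate 1), for apoptosis (0.0795, 0.213, 0.300 and 0.0806 without wild-type replicates 2 or 3 or overexpressing replicates 1 or 3) and for ferroptosis (0.281, 0.275 and 0.0548 without wild-type replicate 1 or overexpressing replicates 2 or 3). So did the stricter filter, limma-voom and a replicate block for each of the 3 lists. The cytokine and apoptosis calls were also lost with haemoglobin, immunoglobulin and mitochondrial genes left out, the cytokine call without a filter and the apoptosis call with RLE or upper-quartile scaling. The call held in 5, 3 and 7 of 15 alternatives for cytokines, apoptosis and ferroptosis.

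Stromal and mitochondrial lists shifted by small amounts, with 0 members changed over each list alone. The median log2 fold change was -0.18 for collagen and matrix genes and -0.18 for fibroblast markers, and 4 genes stand in both lists. Without wild-type replicate 2 the medians were -0.019 and -0.053, and without wild-type replicate 1 they were -0.36 and -0.29. Ratios were 0.629 for the cross-linking enzyme gene Lox, 0.822 for Col4a2, 0.689 for Pdgfra and 0.804 for Inmt. All 22 nuclear genes of oxidative phosphorylation had positive values, with a median of 0.12; Cox5b was 1.15-fold and Ndufa9 1.15-fold higher. Transcripts of the mitochondrial genome had a median of -0.16, with ratios of 0.671 for mt-Atp6 and 0.678 for mt-Co3. Without 1 library the log2 fold change ran from -0.77 to -0.17 for mt-Atp6 and from -0.87 to -0.19 for mt-Co3. The camera adjusted p was 0.00768, 0.0463, 0.00520 and 0.0438 in that order of lists, and with an estimated correlation the adjusted p was 0.784, 0.687, 0.650 and 0.760. Calls were lost for collagen without wild-type replicates 2 or 3 or overexpressing replicate 1 (adjusted p of 0.786, 0.204 and 0.205), for fibroblasts without those or overexpressing replicate 3 (0.744, 0.118, 0.178 and 0.0623) and for oxidative phosphorylation without wild-type replicate 2 or overexpressing replicate 1 (0.0586 and 0.0809). The mitochondrial median was -0.29 without wild-type replicate 3, turned to 0.086 without wild-type replicate 1 (adjusted p = 0.528) and lost its call without overexpressing replicates 2 or 3 (0.219 and 0.165). The fibroblast and mitochondrial calls were also lost with the stricter filter and with limma-voom.

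Markers of muscle, fat and mucus-producing cells were higher as lists but varied widely between libraries, and few members changed. Skeletal muscle markers had a median log2 fold change of 2.06 and cardiac muscle markers one of 1.21. Fat markers had a median of 1.08 and mucin and goblet cell genes one of 0.69. The camera adjusted p was 5.47e-05, 0.000425, 0.0213 and 0.00506, and with an estimated correlation the adjusted p was 0.513, 0.678, 0.687 and 0.655. Over each list alone 0 of 15 cardiac muscle, 0 of 11 fat and 0 of 15 mucin and goblet cell members changed. Acta1, the actin gene of skeletal muscle, reached 19.4 CPM in overexpressing replicate 3 and at most 0.661 CPM elsewhere. With Myl1 (6.89-fold) it was 1 of 2 of 8 skeletal muscle members that rose over the list alone; without that library the list median was 1.19 (adjusted p = 0.00432), and without wild-type replicate 3 it was 3.35. The cardiac hormone gene Nppa reached 78.2 CPM in overexpressing replicate 2 and at most 4.33 CPM elsewhere, and Tnnc1 was 2.83-fold higher with overlapping groups. Without 1 library the Tnnc1 log2 fold change ran from 0.37 to 3.16. Plin1, a gene of the fat droplet, reached 7.39 CPM in overexpressing replicate 2 and at most 1.42 CPM elsewhere. Cox8b, of the fat list, was 2.12-fold higher, at 4.38 CPM in that library and at most 1.52 CPM elsewhere. Without 1 library the Cox8b log2 fold change ran from 0.38 to 1.34. Without wild-type replicate 3 the cardiac median was 2.98 (adjusted p = 4.21e-16). Without overexpressing replicate 2 the medians were 0.050 for cardiac muscle (adjusted p = 0.219), -0.058 for fat (adjusted p = 0.900) and 0.44 for mucins (adjusted p = 0.212). The calls were also lost without wild-type replicate 2 for cardiac muscle (median 0.65, adjusted p = 0.0505) and without wild-type replicate 1 for fat (adjusted p = 0.286) and mucins (median 0.44, adjusted p = 0.0837). The stricter filter ended the calls for fat and mucins, and limma-voom that for fat. Muc5b, a gel-forming mucin gene, was 5.25-fold higher (95% interval 2.02 to 13.7), at 14.1 ± 9.75 against 74.3 ± 43.5 CPM (SD, n = 3 each), with all 3 overexpressing libraries above the wild-type ones and an edgeR adjusted p of 0.216. Tff2, a secreted partner of mucins, was 3.82-fold higher with overlapping groups. Mucin levels were -0.58, -0.09 and 0.67 in the wild-type and 0.90, 1.74 and 0.17 in the overexpressing libraries. Club cell markers, which did not pass camera, were at -0.72, -0.34 and 1.07 and at 1.13, 1.33 and 0.41, with the same order of libraries within each group. Why these airway transcripts varied was not tested.

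In all, 26 of the 53 lists tested passed camera, 12 of them higher and 14 lower, and 27 did not. Responses that smoke is known to engage were among the 27. The median log2 fold change was 0.041 for NRF2 antioxidant targets, with 0 of 24 members changed over the list alone, -0.094 for aryl hydrocarbon receptor targets and xenobiotic metabolism, with 1 of 16 (Tiparp, with a log2 fold change of -0.31 ± 0.072 SE), -0.10 for proteases and antiproteases, with 0 of 24, and 0.32 for neutrophil markers, with 0 of 16. The camera adjusted p was 0.273, 0.0908, 0.0908 and 0.180 for these. Osgin1 and Cbr3, which NRF2 induces, had log2 fold changes of 0.23 ± 0.096 and 0.26 ± 0.135 (SE). Without adjustment 28 lists had a camera p under 0.05. With an estimated correlation 0 lists passed, and 5 had an unadjusted p under 0.05.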

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

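The Fto difference kept its size and call under every alternative (log2 fold change 3.27 to 3.37). With RLE or upper-quartile scaling or the stricter filter the 16 called genes became 16, 17 and 15. Without a filter on low counts 287 genes passed (252 higher, 35 lower, 199 at least 2-fold), all 16 among them; the prior degrees of freedom of that fit rose from 3.62 to 11.1, beside 4 residual ones. With haemoglobin, immunoglobulin and mitochondrial genes left out 31 passed (24 higher, 7 lower, 26 at least 2-fold), with DESeq2 420 (338 higher, 82 lower, 232 at least 2-fold) and with limma-voom 5 (2 higher, 3 lower, 4 at least 2-fold); the causes were not tested. At an adjusted p of 0.01, 1 gene passed, and at 0.1, 70. With 1 library left out, the count ran from 1 to 49, from 1 to 45 for higher genes, from 0 to 4 for lower genes and from 1 to 47 for genes changed at least 2-fold. It was 1 without wild-type replicates 2 or 3 or overexpressing replicate 2, 6 and 49 without overexpressing replicates 3 and 1, and 11 without wild-type replicate 1. Of those 11, only 5 were among the original 16. All of the 6 were among the 16, and the 49 held all 16. Fewer libraries leave fewer residual degrees of freedom, which does not account for the higher count of 49.

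With the replicate number as a block, 2 genes passed, both higher and both at least 2-fold (Fto and Gzmk), and 0 were lower. Over all genes, libraries with the same number did not clearly deviate together (correlations of 0.108, -0.308 and -0.308). This cannot exclude a shared litter, batch or day, which the labels do not state. Deviations of single libraries, such as those of muscle transcripts, also enter the correlations.

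Among lists, 26 passed with the preset correlation and 0 with an estimated one (smallest adjusted p 0.173; 5 lists under 0.05 unadjusted) or with directional fry (smallest adjusted p 0.125; 10 lists under 0.05 unadjusted), while 12 passed fry's mixed test. The T cell, cytotoxic cell, cell cycle, interferon, glucocorticoid, immediate early, alveolar type 1 and 2, surfactant, endothelial, mesothelial, skeletal muscle and TGF-beta lists passed camera in every other alternative, the last with an adjusted p of up to 0.0497. Without 1 library the mitochondrial genome list ran from -0.2852 to 0.0859, the latter without wild-type replicate 1 (adjusted p = 0.528). The medians of the cytokine and fat lists turned to -0.134 without overexpressing replicate 1 and -0.058 without replicate 2, past no threshold. No named gene turned: over all alternatives 693 of their values kept their side of the threshold, 48 passed only in the alternative and 78 only in the original fit. No scaling moved the median of all genes by 0.1 or more.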

Other observations

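Genes outside the naming rule in this part were chosen after their values were seen, as were all tests here except the count over splits.

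Some effector lymphocyte genes outside the naming rule had large fold changes without passing the threshold over all genes. The cytotoxic effectors Gzmb and Prf1 were 13.6-fold (95% interval 4.88 to 37.9) and 4.43-fold (95% interval 2.46 to 7.97) higher, and Gzmk was 22.3-fold higher (95% interval 5.96 to 83.2), all in 3 of 3 overexpressing libraries. Cxcr3, a chemokine receptor of effector T cells, was 4.73-fold higher (95% interval 2.60 to 8.62). Their edgeR adjusted p lay between 0.0970 and 0.117. Ncr1, the NK cell receptor NKp46, was 2.08-fold higher with a 95% interval of 0.845 to 5.13, and Foxp3, the regulatory T cell factor, 1.01-fold (95% interval 0.371 to 2.73). The gamma-delta T cell receptor genes Trdc and Trgc1 had ratios of 0.668 (95% interval 0.396 to 1.13) and 0.655 (95% interval 0.368 to 1.17). The tissue residence genes Itgae and Cd69 had ratios of 0.770 (95% interval 0.529 to 1.12) and 1.15 (95% interval 0.627 to 2.10). Cd4 was 2.13-fold higher (95% interval 1.28 to 3.52; adjusted p = 0.282). The Cd8a to Cd4 ratio was 0.879, 0.412 and 1.11 in the wild-type and 1.64, 3.49 and 2.30 in the overexpressing libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 samples can give).

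Of the interferon-gamma targets, Gbp2, Iigp1 and Irgm1 were highest in overexpressing replicate 1 (345.8, 387.2 and 184.9 CPM), the overexpressing library with the lowest T cell level (1.06). In replicate 3, with the highest (1.82), they were at 150.6, 111.2 and 80.3 CPM. The class I antigen presentation genes H2-K1, H2-D1, B2m and Psmb8 were highest in overexpressing replicate 3 among the overexpressing libraries, Tap1 and Psmb9 in replicate 1, and all of them were lowest in replicate 2. Tap1, the peptide transporter gene, was at 59.8 ± 12.6 against 112.3 ± 17.2 CPM (SD, n = 3 each), 1.88-fold higher with an adjusted p of 0.118 from edgeR. T cell receptor beta variable segments gave 73 to 131 counts per wild-type and 251 to 674 per overexpressing library. Their effective number, the inverse Simpson index, was 15.9 ± 1.11 against 13.4 ± 2.45 (SD, n = 3 each; two-sided exact permutation p = 0.2). The segment with the most counts differed between the overexpressing libraries: Trbv16 with 11.6%, Trbv3 with 17.1% and Trbv12-2 with 17.7%.

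The real grouping called 16 genes with edgeR, and the other splits of the 6 libraries into 3 and 3 called at most 2; 1 split, the real one, gave as many. Without adjustment the real grouping was not the largest: it had 1603 genes with an edgeR p under 0.05, and the split that put wild-type replicate 1 with overexpressing replicates 1 and 3 had 2112, of which 0 passed adjustment. With 10 splits the share cannot fall under 0.05.

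The higher T and cytotoxic transcripts were set against 3 other sources of lymphocytes in the tissue. If more blood had stayed in the overexpressing lungs, red cell transcripts would have risen with the T cell list, but the erythroid list had a median log2 fold change of 0.13 with an upper quartile of 0.21, below the lower quartile of 0.95 of the T cell list. Lymph node tissue would have brought B cells, whose list had a median of -0.019 and an upper quartile of 0.043. Thymus tissue would have brought Rag1, Rag2, Dntt and Ptcra, which had 6 counts in the overexpressing and 14 in the wild-type libraries, beside 5970 and 1595 counts of Cd3d, Cd3e and Cd3g. Other members of the thymus list were not all flat: Prss16 had 56 counts in overexpressing replicate 3 and 9 to 19 elsewhere, and Ccr9, which mature lymphocytes also carry, 120 and 45 to 73. In that library Psmb11, of the thymic cortex, had 0. A candidate explanation that remains, and was not tested, is more effector CD8 T cells in the FTO-overexpressing lungs. Lung RNA does not separate more cells from more transcript per cell, and which cells the cell cycle transcripts came from was not tested. These libraries do not separate FTO itself from how its overexpression was delivered, nor cells in the tissue from cells in its vessels.

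The lower Klf4, Irx1 and Car14 could reflect resident cells diluted by lymphocytes. Over 72 markers of alveolar, endothelial, fibroblast and smooth muscle cells the median log2 fold change was -0.15 and the lower quartile -0.26. The highest upper 95% bound of the 3 genes was -0.69, below that quartile. The 3 genes were picked for their fall in these same data, so the comparison does not exclude dilution. Mesothelial markers, outside the 72, had a median of -0.72 and a lower quartile of -1.31, with list levels that overlapped between the groups. A change inside resident cells or a loss of 1 small population stays open and was not tested, as does handling of the tissue for Klf4, which is an immediate early gene.

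The muscle signals could reflect different amounts of heart or pulmonary vein muscle in the dissections, and skeletal muscle in that of overexpressing replicate 3. Cardiac muscle levels spread over 3.64 log2 units among the wild-type libraries, more than the difference of 1.57 between group means. The fast skeletal fibre genes Myh1, Myh2, Myh4, Tnnc2 and Pvalb had 905 counts in overexpressing replicate 3 and at most 14 in any other library. In overexpressing replicate 2 they had 6 counts, although the level of the skeletal muscle list there was 1.77. No biological explanation was tested for the muscle signals.

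Some genes differed between libraries of 1 group more than between groups. Dbp, a clock output gene, was at 8.47 CPM in wild-type replicate 3 and at 66.6 and 67.0 CPM in the other wild-type libraries. Zbtb16, which glucocorticoids induce, was at 15.2, 140.3 and 169.3 CPM in the wild-type and 91.5, 19.3 and 16.0 CPM in the overexpressing libraries. Bpifb1, a secreted airway protein gene, ran from 0.379 to 41.3 CPM among the wild-type libraries and from 17.7 to 183.7 CPM among the others. Ltf had 1105 to 3521 counts in the wild-type and 1723 to 5088 in the overexpressing libraries.

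The other lists that did not pass camera are given as median log2 fold changes. Among immune lists they were -0.26 for dendritic cells, 0.14 for mast cells, basophils and eosinophils, -0.26 for plasma cells and immunoglobulins, 0.13 for class II presentation, -0.14 for complement, 0.048 for NF-kB targets and 0.15 for the inflammasome. Among other cell types they were 0.18 for club cells, 0.070 for ciliated cells, -0.20 for lymphatic endothelium, -0.029 for smooth muscle and pericytes, -0.17 for nerve and neuroendocrine cells, 0.038 for platelets and 0.13 for erythroid genes. They were -0.15 for p53 targets and senescence, -0.028 for the unfolded protein response, -0.039 for autophagy and lysosome, 0.051 for hypoxia and glycolysis, -0.052 for lipid uptake and oxidation, 0.028 for the clock and 0.11 for ribosomal proteins. Within them 1 member changed over the list alone in each of 3 lists: Lmnb1 (0.89 ± 0.154, SE), a nuclear lamina gene higher in dividing cells, the hedgehog antagonist gene Hhip (-0.74 ± 0.131) and Ptgs2 (-0.999 ± 0.186), and 0 members changed in the others. In 8 lists that did not pass, the median, mean and camera direction did not share a sign. The basal cell, cartilage and thymus lists had too few members above the filter; Krt5 had 18 counts in overexpressing replicate 2 and at most 1 elsewhere, Acan 14 and 0.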
